A study of Mus musculus with 10 samples.

How the data were processed

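Total RNA from the spleens of 10 leukemic mice, 5 per genotype, was hybridised to Affymetrix mouse exon arrays after amplification and biotin labelling, per the labels' protocols. Samples were assigned to RARA+/- or RARA+/+ and numbered from their titles, which call them biological replicates; no sex, age or hybridisation batch is given. The deposited table holds an intensity for each probe set and array, made by the authors with RMA, with mm9 named as the genome build, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes, so values of different arrays depend on each other, and low values lie near background and compress differences. The RMA software, its version, the probe set level and its background setting are not given in the sources used here. RMA output is usually on a log2 scale, but the values ranged from about 2 to 19549, so the deposited intensity is on a linear scale, and its log2 was taken without further normalization. All 10 columns were used, and there were no columns of other samples.

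Gene names came from the platform annotation: 208397 probe sets had 1 gene symbol, 3965 had several, and 17219 were not listed and are unnamed here. Of 16299 symbols, 14132 were current in the RefSeq annotation of GRCm38.p6, 2124 were updated through a synonym and 43 were kept as in the platform annotation. That annotation is of another build than the one in the submitters' notes, so it served only for names and neighbours and no position is printed. A gene value is the median of the log2 values of the probe sets with that symbol alone (16277 genes, median of 11 probe sets). Genes with a mean above the 25th percentile, a log2 value of 5.57, were kept, leaving 12207. Probe sets were filtered in the same way at a log2 value of 5.44, leaving 172185. For arrays no count depth exists, and the number of arrays limits the precision.

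Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a 5% false discovery rate (FDR), over genes and over probe sets. The probe set profile was tested with diffSplice (Simes p per gene) in 15107 genes with at least 3 probe sets. For 21 gene lists the mean log2 value of all measured members per array was compared by an exact permutation test over all divisions of the arrays into 5 and 5, two-sided, whose smallest p is 0.00794; over 21 lists that is an adjusted p of 0.167 for a single list, so 4 lists would have to reach it together to pass. Camera with a preset correlation of 0.01 compared each list with other genes, and camera with an estimated correlation and fry were run beside it; fry tests whether the genes of a list move on balance in 1 direction. Principal components were taken from centred kept genes and compared by the same exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

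The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Rara with all its probe sets; up to 10 genes per direction with the largest difference among those that pass, filled up with the genes of lowest p, given as not passing; the 3 members of lowest p in each list; Y-linked and X-inactivation genes as a check of sex; genes near Rara with an unadjusted p under 0.05; the 5 genes of lowest Simes p; and the 5 most variable kept genes. Xist, Ddx3y and Uty are unnamed in the platform annotation and were not analysed here. Both spellings of a renamed gene were listed. The lists cover retinoid receptors, retinoic acid metabolism, primary granules, neutrophils, progenitors, myeloid transcription factors, cell cycle, its inhibitors with p53 targets, interferon response, MYC and ribosome biogenesis, neighbours of Rara, and markers of B, plasma, T, NK, erythroid, platelet, macrophage, dendritic, mast and stromal cells.

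The tests were also tried on simulated data. The gene simulation used the real means and spreads, with 50 genes changed at each size in the same data. The gene test recovered 15, 42, 49 and 50 of 50 at log2 changes of 0.5, 1, 2 and 3. It made 11 false calls among 12207 genes. On simulated arrays with no difference between the groups, diffSplice called 0 of 15107 genes when all probe sets of a gene had equal spread and 579 when each probe set had its own measured spread; a test of each probe set against its own spread called 0 in both cases and recovered 163 of 200 genes given a probe set changed by a log2 value of 2, against 189 with diffSplice.

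Alternatives were the replicate number as a block, each array left out in turn, no filter or a stricter filter on dim genes, the mean of all or of the brighter 50% of probe sets as gene value, quantile normalization or centring of arrays, a trended and robust eBayes, array weights, an ordinary t statistic, genes of chromosomes X and Y left out, other list tests, and scaled genes for the components. Alternatives added later were the level of the Y-linked genes as a covariate, the own-spread profile test and the profile without dim probe sets. Samples with the same replicate number come from different mice.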

Results

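Gene expression was measured in the spleens of 10 leukemic mice that expressed PML-RARA, the fusion protein of acute promyelocytic leukemia, from the Cathepsin G locus, a gene active in promyelocytes. In 5 mice 1 allele of the retinoic acid receptor gene Rara was lost (RARA+/-), and 5 mice kept both alleles (RARA+/+). Each spleen was hybridised to its own exon array, and the table held RMA intensities of 229581 probe sets, of which 208397 carried exactly 1 gene symbol. Median intensities of the arrays lay between 102.35 and 112.25. Gene values of different arrays correlated with Pearson's r between 0.895 and 0.974 across the 12207 genes kept, and no arrays were identical. Values are log2 intensities given as mean ± SD over the 5 mice of a genotype, differences are RARA+/- minus RARA+/+, and folds are RARA+/- over RARA+/+. The number of arrays limits the precision: the median SE of a gene's log2 difference was 0.151.

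The first question was whether Rara itself was lower in the RARA+/- spleens. Rara, on chromosome 11, encodes a nuclear receptor that binds retinoic acid. Over all of its 13 probe sets the Rara gene value did not separate the genotypes, at 7.28 ± 0.26 in RARA+/- and 7.37 ± 0.12 in RARA+/+ spleens (n = 5 each, difference -0.09, SE 0.135, exact permutation p = 0.484, two-sided). In contrast, 2 Rara probe sets were lower in every RARA+/- spleen than in any RARA+/+ spleen. Probe set 4612180 measured 4.81 ± 0.41 in RARA+/- and 6.18 ± 0.45 in RARA+/+ spleens, 38.7% of the RARA+/+ level, and probe set 5534347 measured 6.95 ± 0.27 and 7.66 ± 0.10, 61.1% of it.

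By replicate from 1 to 5, the Rara gene value was 7.13, 7.44, 7.61, 6.94 and 7.29 in RARA+/- spleens and 7.28, 7.51, 7.50, 7.26 and 7.31 in RARA+/+ spleens. The 95% interval of the difference ran from -0.39 to 0.20. Both lower probe sets reached the smallest p that the exact permutation test can give with 5 mice per group, exact p = 0.00794. It became 0.0516 after Benjamini-Hochberg adjustment over the Rara probe sets. With limma, adjusted over the Rara probe sets alone, adjusted p = 0.00207 for 4612180 and 0.00534 for 5534347, whereas over all 172185 probe sets tested both had an adjusted p = 0.917. Probe set 5013671, the brightest of the gene, lay at 9.95 ± 0.23 in RARA+/- and 9.56 ± 0.16 in RARA+/+ spleens, 131% of the RARA+/+ level, and did not pass over the Rara probe sets (limma, adjusted p = 0.131). The remaining 10 probe sets lay between 78.2% and 115% of the RARA+/+ level without passing. Which part of the gene was removed in the targeted allele is not given in the sources used here, and a probe set outside that part is no check of the genotype. All 10 mice also expressed PML-RARA, and whether Rara probe sets read its RARA part was not tested. The values may therefore not measure the mouse gene alone.

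**Figure D1:**
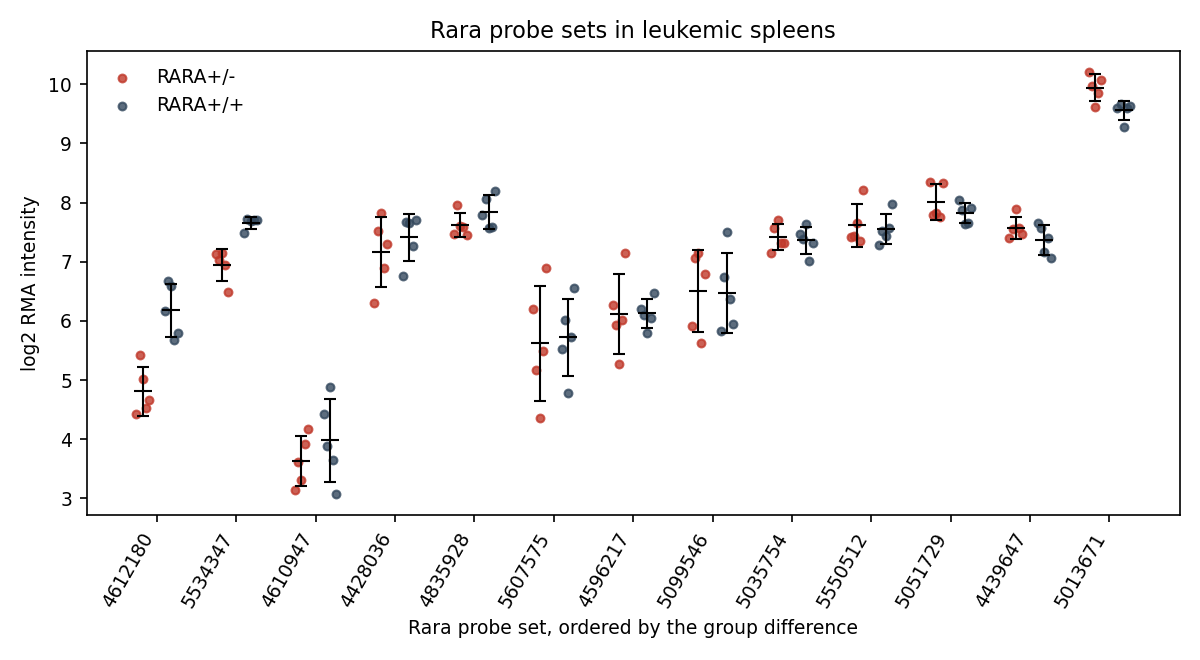
Log2 RMA intensity of the 13 Rara probe sets, ordered along the horizontal axis by the difference between genotypes; points are spleens, and bars are the mean ± SD of the 5 spleens of a genotype. Probe sets 4612180 and 5534347, at the left, show no overlap between RARA+/- and RARA+/+ spleens, while the others overlap.

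The second question was which genes differed between RARA+/- and RARA+/+ leukemic spleens. No gene passed, and the genes with the lowest unadjusted p are therefore given by their values only. Toward higher values in RARA+/- spleens these were led by Fabp4, a fatty acid binding protein of adipocytes and macrophages, at 6.20 ± 0.09 against 5.22 ± 0.41 (n = 5 each, 1.97-fold, or a log2 difference of 1.69 instead of 0.98 when the gene value is the mean of its brighter probe sets). Tfec, a transcription factor of the macrophage lineage, was at 7.95 ± 0.91 against 5.90 ± 0.66 (4.13-fold), and Il1r1, an interleukin receptor, at 6.81 ± 0.59 against 5.23 ± 0.73 (log2 difference 1.58). Toward lower values they were led by the Y-linked gene Eif2s3y, at 4.70 ± 1.86 against 9.0 ± 1.37 (0.0509-fold).

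Of 12207 genes tested with limma, 0 passed 5% FDR (lowest adjusted p = 0.995), and the ordinary t statistic also gave 0. An unadjusted p under 0.05 was found for 513 genes, 253 higher and 260 lower in RARA+/-, where chance alone gives 610. The groups did not overlap in 109 genes, 0.893% of those kept, against 0.794% by chance. Other genes with a low unadjusted p and a higher value in RARA+/- spleens were Ctsb, a lysosomal cysteine protease (8.68 ± 0.20 against 8.04 ± 0.29), and the platelet chemokine Ppbp (8.04 ± 0.42 against 6.70 ± 0.75). The beta-defensin Defb11 was at 6.22 ± 0.41 against 5.35 ± 0.22. Smaller differences were seen in the kallikrein-related peptidase Klk9 (1.52-fold), Tifab (1.49-fold), Ankrd36 (1.48-fold) and Cdcp1 (1.35-fold). Among the genes with a lower value were 3 on chromosome X: Itm2a (5.29 ± 0.44 against 6.20 ± 0.35), the Fanconi anaemia gene Fancb (6.32 ± 0.10 against 6.84 ± 0.29) and BC065397 (5.45 ± 0.23 against 6.05 ± 0.23). The muscarinic receptor gene Chrm5 was at 0.558-fold, Dcbld1 at 0.547-fold and Zfp420 at 0.749-fold. C1qtnf4 was at 0.659-fold, but its log2 difference was 0.09 when taken from its brighter probe sets. With the mean of all or of the brighter probe sets as gene value, the log2 differences also shrank to -0.29 for Dcbld1, -0.30 for Chrm5, -0.15 for Zfp420, 0.44 for Defb11, 0.39 for Ctsb, 0.34 for Tifab and 0.28 for Cdcp1. Of 91 named genes compared in this way, 45 changed sign or moved by over 1.5 times on the log2 scale, as did 40 of 92 with a spleen left out and 48 of 92 with the Y-linked genes as a covariate. Zfp120 (0.512-fold) and the clathrin adaptor gene Ap2m1 (0.685-fold) rested on 1 probe set each. The same test on simulated data with these spreads recovered 30% of genes changed by a log2 difference of 0.5. It recovered 84% of those changed by 1 and 98% of those changed by 2. There 50 genes at each size were changed at once, which loosens the adjusted threshold. A gene changed alone would be recovered less often. Of 172185 single probe sets, limma and its ordinary t statistic passed 0 (lowest adjusted p = 0.917 with limma). An unadjusted p under 0.05 was found for 9313, where chance gives 8609. Without RARA+/+ replicate 1, limma passed 1, a probe set of Eif2s3y.

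The next question was whether genes of the leukemic myeloid cells differed as groups, and here the gene lists lay close together in the genotypes. Genes of the primary granules, the storage granules of promyelocytes, stood at 10.30 ± 0.15 in RARA+/- and 10.26 ± 0.14 in RARA+/+ spleens (n = 5 each), with 9 of 17 members higher. Among them, the granule protease gene Ctsg was at 11.33 ± 0.51 against 11.70 ± 0.39, Ctsc at 7.29 ± 1.00 against 6.49 ± 1.26, and Cd63 at 0.906-fold. Secondary granule and mature neutrophil genes stood at 9.61 ± 0.54 and 9.63 ± 0.66, with 9 of 27 higher, and stem and progenitor genes at 6.67 ± 0.11 and 6.66 ± 0.07, with 14 of 24 higher. None of these groups passed.

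Exact permutation tests of the list means gave exact p = 0.706 for primary granule genes, 0.944 for neutrophil genes and 0.841 for stem and progenitor genes. The camera test gave primary granule and progenitor genes the opposite sign, also without passing. Named members of the neutrophil list were Chil3, a secreted lectin (2.03-fold), the growth factor receptor Csf3r (8.10 ± 0.39 against 8.39 ± 0.24) and Anxa1 (10.90 ± 0.54 against 11.25 ± 0.32). Of the progenitor list, the transcription factor Myb was at 9.81 ± 0.25 against 10.20 ± 0.29, Cd34 at 8.50 ± 0.29 against 8.81 ± 0.28 and Erg at 8.64 ± 0.11 against 8.87 ± 0.25. Myeloid transcription factors differed by -0.13 (10 of 22 higher, exact p = 0.325), with Jun at 7.08 ± 1.45 against 8.79 ± 1.16, Junb at 6.33 ± 0.50 against 7.02 ± 0.30 and Cebpb at 6.84 ± 0.26 against 6.42 ± 0.21. Cell cycle inhibitors and p53 targets differed by -0.14 (9 of 19 higher, exact p = 0.167), with the antiproliferative gene Btg2 at 8.42 ± 1.24 against 9.48 ± 0.18, the death receptor gene Fas at 6.41 ± 0.46 against 7.04 ± 0.31 and Mdm2 at 8.70 ± 0.35 against 9.08 ± 0.29. Cell cycle genes differed by 0.0014 (18 of 35 higher, exact p = 1), with Ube2c at 0.781-fold, Plk1 at 1.20-fold and Ccnb2 at 0.848-fold. MYC and ribosome biogenesis genes differed by 0.05 (12 of 19 higher, exact p = 0.817), with Cad at 1.12-fold, Rrp9 at 0.890-fold and Odc1 at 1.13-fold.

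Retinoid genes were examined as the pathway of the targeted receptor. Retinoid receptors and co-regulators, Rara included, differed by -0.05, with 5 of 15 members higher in RARA+/- spleens. The co-repressor Ncor1 was at 9.78 ± 0.24 against 10.03 ± 0.16 and the co-activators Ncoa2 and Ncoa1 at 0.904-fold and 0.904-fold (n = 5 each). Genes of retinoic acid metabolism and retinoic acid induced genes differed by 0.06, with 13 of 22 higher. Fabp5, a carrier of fatty acids and retinoic acid, was at 7.17 ± 0.34 against 6.47 ± 0.67, the retinaldehyde reductase Dhrs3 at 7.45 ± 0.19 against 7.12 ± 0.21, and Rdh11 at 6.66 ± 0.26 against 7.16 ± 0.44. Genes near Rara on chromosome 11 differed by 0.01, with 11 of 23 higher and a median of -0.00. Gjd3, the only one of them with an unadjusted p under 0.05, was measured by 1 probe set (6.78 ± 0.20 against 6.35 ± 0.36), and Wipf2 and Nr1d1 were at 0.866-fold and 1.13-fold. Exact permutation tests gave exact p = 0.294 for the receptors, 0.357 for the metabolism and induced genes and 0.746 for the neighbours.

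The remaining lists mark the other cells a spleen can hold, and most of their members were higher in RARA+/- spleens. Erythroid markers showed the largest list difference, 0.67 (SE 0.448). All 20 measured members were higher on average, among them the globin gene Hbb-b1 (12.84 ± 0.38 against 11.55 ± 1.55, a log2 difference of 1.29, or 0.73 without RARA+/+ replicate 5), the transferrin receptor Tfrc (10.10 ± 0.39 against 9.39 ± 0.65) and the erythroid transcription factor Klf1 (6.32 ± 0.09 against 5.98 ± 0.28). Of the platelet markers 12 of 15 were higher, led by the platelet chemokines Ppbp (2.52-fold) and Pf4 (7.04 ± 0.61 against 5.90 ± 0.63, 2.21-fold). Of the macrophage and monocyte markers 24 of 28 were higher, including Nr1h3 and the complement gene C1qb, while the receptor Cd14 was lower. These lists passed camera only with its preset correlation.

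By camera, 7 of 21 lists passed 5% FDR with the preset correlation of 0.01, all toward higher values in RARA+/- spleens, and 0 of them with an estimated correlation. The 7 were erythroid markers (4 of 5 RARA+/- spleens above the RARA+/+ mean, adjusted p = 3.54e-09), macrophage and monocyte markers (difference 0.24, 5 of 5 spleens, adjusted p = 0.000375), and plasma cell markers (0.28, 8 of 8 members higher, 5 of 5 spleens, adjusted p = 0.00452). T cell markers (0.18, 15 of 23 members, 3 of 5 spleens, adjusted p = 0.00500), platelet markers (0.21, 5 of 5 spleens, adjusted p = 0.0165), NK cell markers (0.33, 15 of 16 members, 3 of 5 spleens, adjusted p = 0.0265), and stroma and endothelium markers (0.10, 17 of 25 members, 4 of 5 spleens, adjusted p = 0.0475) had the smaller margins. The spleen counts do not set these lists apart. Lists that did not pass had from 1 to 5 of 5 spleens above the RARA+/+ mean, with dendritic cell markers at 5 and cell cycle genes at 4. With an estimated correlation, limma's adjusted p = 0.530 for the erythroid, macrophage, plasma cell and platelet markers, 0.602 for T cell markers and 0.601 for NK cell and stroma markers. The exact permutation test passed 0 of 21 lists after adjustment, but it could hardly pass any, since a single list that separates the genotypes fully has an adjusted p = 0.167 and 4 such lists are needed. Stroma and endothelium markers had the lowest p (exact p = 0.0397, adjusted p = 0.583), and the erythroid list had exact p = 0.167. The rotation test fry also passed 0 lists, and 0 of them had an unadjusted p under 0.05. Without RARA+/+ replicate 3, camera with the preset correlation passed 3 lists, those of the plasma cells, erythroid cells and macrophages.

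Within the lists, Ppbp and Pf4 passed when adjusted over the list alone (limma, lowest adjusted p = 0.0167), and no other list had a member that did. That adjustment does not cover the 21 lists, so chance alone can give 1 list with a passing member. Over all genes 0 passed. Among lymphoid genes, the cytotoxic granule gene Gzmb was at 6.82 ± 0.76 against 5.90 ± 0.61 (n = 5 each), Gzma at 7.68 ± 0.94 against 6.80 ± 1.31 and Prf1 at 1.16-fold, while the T cell genes Bcl11b, Cd5 and Thy1 were at 1.32-fold, 1.24-fold and 2.56-fold. The log2 difference of Thy1, 1.35, was 0.83 without RARA+/- replicate 5. Of the plasma cell genes, Jchain was at 7.72 ± 0.81 against 6.90 ± 1.02, Derl3 at 1.25-fold and Sdc1 at 1.23-fold. Nr1h3 was at 6.26 ± 0.20 against 5.87 ± 0.09, C1qb at 6.80 ± 0.44 against 6.29 ± 0.40 and Cd14 at 6.18 ± 0.29 against 6.85 ± 0.60. The platelet integrin Itgb3 was at 1.23-fold, and of the stroma the matrix genes Fn1 and Col1a1 were at 1.93-fold and 1.12-fold and the sinusoidal receptor Stab2 at 1.23-fold. B cell markers differed by 0.01 (9 of 17 higher, exact p = 0.984), with Ighm at 9.10 ± 0.84 against 8.67 ± 0.94, Pou2af1 at 1.17-fold and Vpreb3 at 0.913-fold. Dendritic cell markers differed by 0.13 (16 of 19 higher, exact p = 0.429), with Cd209a at 1.20-fold, Ciita at 1.24-fold and Flt3 at 1.38-fold. The log2 difference of Flt3, 0.47, was 0.07 without RARA+/- replicate 5, and that of Ciita, 0.31, was -0.14 in 1 alternative. Mast cell and basophil markers differed by 0.27 (10 of 12 higher, exact p = 0.437), with Cma1 at 1.20-fold, Ms4a2 at 1.42-fold and Tpsab1 at 0.933-fold. Interferon response genes differed by 0.16 (15 of 25 higher, exact p = 0.302), with Cxcl9 at 1.24-fold, Ifit2 at 1.28-fold and Gbp3 at 1.54-fold. With the level of the Y-linked genes as a covariate, a setting chosen after seeing the data, the log2 differences of Gzma (-0.50), Jchain (-0.29), Ighm (-0.70), Gbp3 (-0.09) and the granule gene Ctsc (-0.22) turned negative, and none passed.

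**Figure D2:**
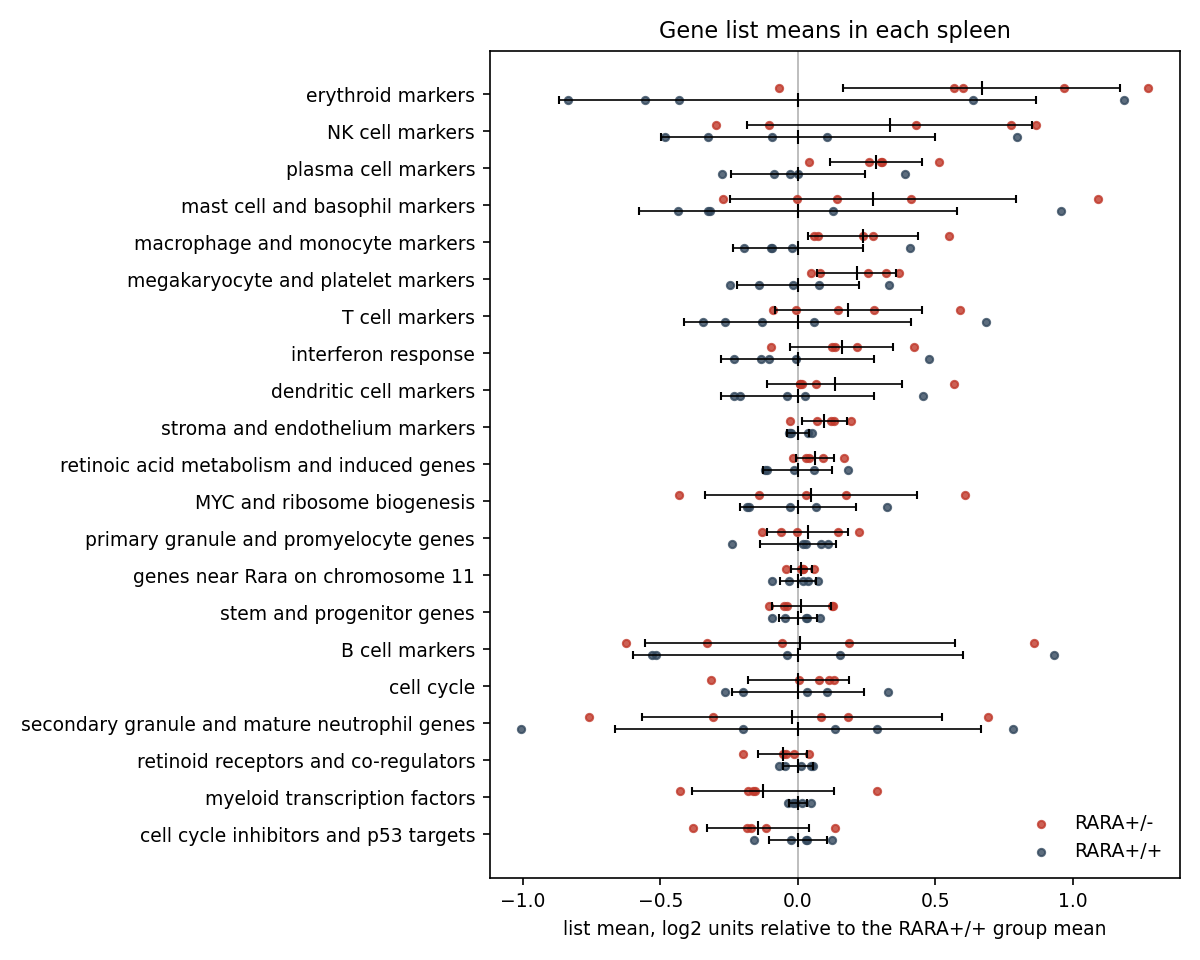
Mean log2 value of each of the 21 gene lists in each spleen, relative to the mean of the RARA+/+ spleens, on the horizontal axis in log2 units; points are spleens, and bars are the mean ± SD of the 5 spleens of a genotype. Erythroid markers show the largest difference, 0.67, and also wide ranges that overlap between genotypes.

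The exon arrays also allowed a test of whether the probe sets of a gene moved differently from each other between the genotypes. The genes with the lowest p each had a probe set that stood apart from the rest of its gene. In Fbrsl1, probe set 5167156 was higher in RARA+/- spleens (5.14 ± 0.63 against 3.50 ± 0.88, n = 5 each). In Actn2, which encodes a cross-linker of actin filaments in muscle, probe set 4721230 was lower (3.37 ± 0.93 against 5.44 ± 0.66). Of Rabep1, an endosomal transport gene, probe set 5463178 was higher (6.59 ± 0.40 against 4.81 ± 1.48) and 5305523 lower (5.11 ± 0.74 against 6.28 ± 0.48). In the kinesin light chain gene Klc4, probe set 5078919 was higher (5.21 ± 0.60 against 3.71 ± 0.87). The Fbrsl1, Actn2 and Klc4 probe sets were dim, with means in both genotypes at or under the log2 floor of 5.44, which this test did not apply.

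Runx3, a transcription factor of T cells and myeloid cells, had probe set 5146074 at 7.17 ± 0.33 against 5.87 ± 0.42 and probe set 4805160 at 7.75 ± 0.27 against 8.36 ± 0.31, both without overlap between the genotypes. The gene values of these 5 genes differed by little. Runx3 was at 7.28 ± 0.26 against 7.44 ± 0.25 and Fbrsl1 at 7.24 ± 0.18 against 7.14 ± 0.04. Klc4 was at 6.94 ± 0.09 against 6.82 ± 0.07, Rabep1 at 7.53 ± 0.18 against 7.52 ± 0.15 and Actn2 at 5.63 ± 0.13 against 5.63 ± 0.25. By limma's diffSplice, 269 of 15107 genes passed 5% FDR (lowest adjusted p = 3.56e-08), and 1790 had an unadjusted p under 0.05 where chance gives 755. Rara was among those that passed, at rank 169 with adjusted p = 0.0186, its probe set 4612180 lying apart from the others. These calls rest on 1 spread shared by the probe sets of a gene. When each probe set was tested with limma against its own spread, 0 genes passed (lowest adjusted p = 0.642, 1031 genes at an unadjusted p under 0.05). With dim probe sets left out 68 passed, and with the level of the Y-linked genes as a covariate 625, all settings chosen after seeing the data. The Rara call was lost in the own-spread test (adjusted p = 0.642), with the covariate (adjusted p = 0.0548) and without any 1 of 6 spleens, RARA+/- replicates 1, 4 and 5 and RARA+/+ replicates 1, 2 and 3 (limma, adjusted p = 0.0531 to 0.112).

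Across all kept genes, the spleens did not sort by genotype. The 2 spleens highest on the first principal component were replicate 2 of RARA+/- (32.2) and replicate 2 of RARA+/+ (29.0). The genes pulling toward that end were led by the immunoglobulin gene Ighg1 and the eosinophil granule gene Prg3, with the T cell receptor gene Trgv3 leading the opposite end. These were also among the most variable genes: Ighg1 ranged from 5.45 to 11.7, Prg3 from 5.53 to 11.5 and Trgv3, measured by 1 probe set, from 4.57 to 12.4. The matrix gene Postn ranged from 4.4 to 11 and Eif2s3y from 3.06 to 10.2. Component 1 held 26.5% of the variance and differed by 5.38 between the genotypes (exact permutation p = 0.659), and component 2 held 19.1% (exact permutation p = 0.698, adjusted over both components 0.698).

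**Figure D3:**
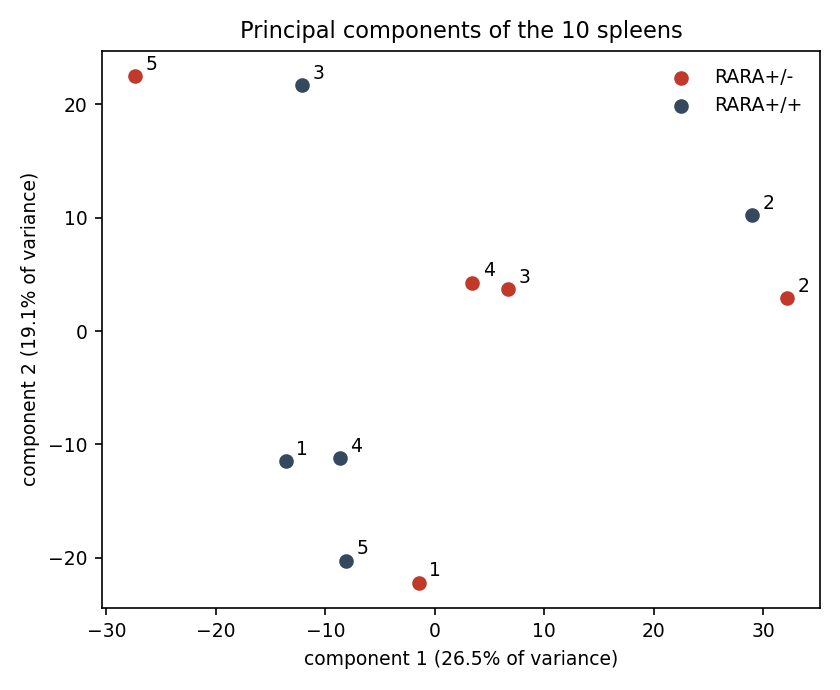
Scores of the 10 spleens on component 1 (horizontal, 26.5% of the variance) and component 2 (vertical, 19.1%) of the 12207 kept genes; each point is a spleen with its replicate number, coloured by genotype. RARA+/- and RARA+/+ spleens are intermixed, and replicate 2 of each genotype lies at the right.

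Y-linked genes were read out as a check of the sex of the mice, which the labels do not give. Eif2s3y, a translation factor gene, was at 3.69, 3.30 and 3.06 in RARA+/- replicates 2, 3 and 4, and at 8.97, 9.79, 9.38 and 10.16 in RARA+/+ replicates 2 to 5. The other 3 spleens lay in between: RARA+/- replicate 1 at 6.66, RARA+/- replicate 5 at 6.79 and RARA+/+ replicate 1 at 6.68. The histone demethylase gene Kdm5d was at 4.51 to 4.85 in the first set, at 7.43 to 8.16 in the second, and at 5.87, 7.24 and 5.84 in those 3. Neither gene passed (limma, adjusted p = 0.995 for both). Y-linked expression thus ran partly along the genotypes. The 3 genes of chromosome X with a lower value in RARA+/- spleens kept to the genotype also at an intermediate Eif2s3y level. Itm2a, Fancb and BC065397 were at 6.36, 7.01 and 5.79 in RARA+/+ replicate 1. They were at 4.74, 6.17 and 5.36 in RARA+/- replicate 1. As these genes were named for their low p between the genotypes, this is no test of a link to Y-linked expression.

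**Figure D4:**
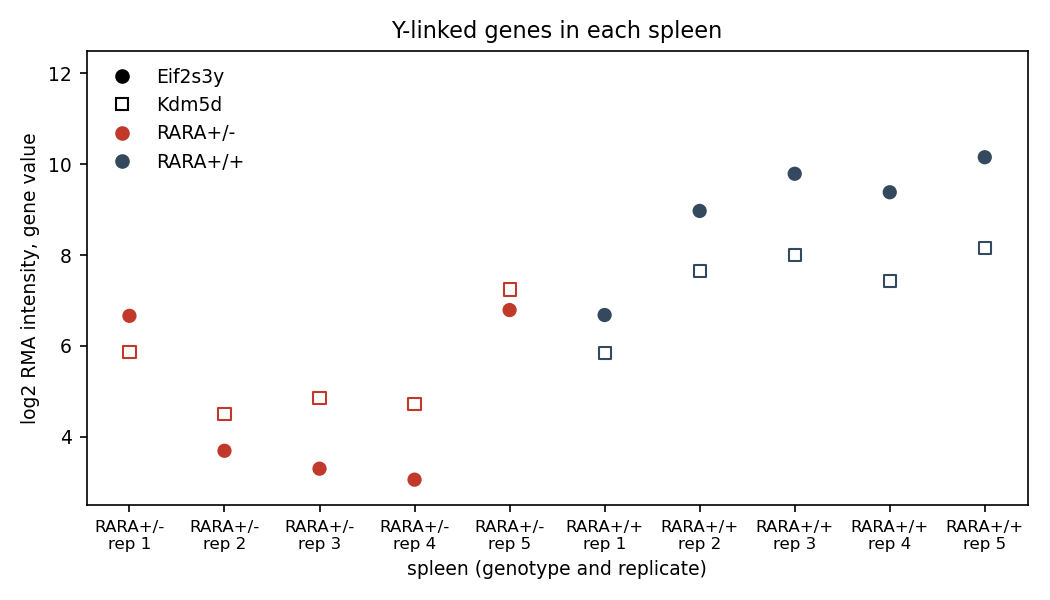
Log2 gene values of the Y-linked genes Eif2s3y (filled circles) and Kdm5d (open squares) in each of the 10 spleens, coloured by genotype, on a vertical axis of log2 RMA intensity. RARA+/- replicates 2 to 4 are lowest for both genes, RARA+/+ replicates 2 to 5 are highest, and RARA+/- replicate 5 has a Kdm5d value close to the high spleens with an Eif2s3y value of 6.79.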

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

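The rule for finding values apart from their group was fixed before the results were seen, and no test was chosen for them afterwards. Within each group of 5 spleens, the named genes, list means, Rara probe sets and components were searched with Dixon's ratio (critical value 0.71). Of 260 groups searched, 17 held such a value where chance at about 1 in 20 gives 13, so these values are given without a cause.

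Among single genes, RARA+/- replicate 5 held Thy1 at 11 (other RARA+/- spleens 7.97 to 8.71), Cad at 7.38 (6.77 to 6.90) and Hbb-b1 at 12.19 (12.90 to 13.11). Il1r1 was 7.87 in RARA+/- replicate 4 (6.47 to 6.64), Ctsc 9.05 in RARA+/- replicate 2 (6.62 to 7.11) and Ncoa2 7.84 in RARA+/- replicate 3 (8.08 to 8.17). In RARA+/+ replicate 2, Jun was 6.75 (9.0 to 9.54) and C1qb 6.99 (6.01 to 6.27). In RARA+/+ replicate 5, Cd63 was 12.29 (12.51 to 12.58) and Dhrs3 7.49 (6.98 to 7.08).

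Among list means, primary granule genes were at 10.02 in RARA+/+ replicate 5 (10.28 to 10.37), cell cycle genes at 8.28 in RARA+/- replicate 1 (8.59 to 8.72), macrophage and monocyte markers at 6.96 in RARA+/+ replicate 2 (6.35 to 6.53) and dendritic cell markers at 7.11 in RARA+/- replicate 2 (6.55 to 6.61). Rara probe set 5013671 was at 9.27 in RARA+/+ replicate 3 (9.60 to 9.67) and Rara probe set 5534347 at 7.48 in RARA+/+ replicate 1 (7.69 to 7.72). Component 1 was 29.0 in RARA+/+ replicate 2 (-13.6 to -8.08).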

How the results depend on the processing

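The own-spread profile test, the profile without dim probe sets, the Y-linked covariate and the alternatives of the camera count and of the 2 Rara probe sets were chosen after the results were seen; the rest were planned. Genes passing stayed 0 in all 22 alternatives. However, the lowest limma adjusted p, 0.995 with all spleens, fell as far as 0.0616 when a single spleen was left out. Probe sets passing ranged from 0 to 1 when spleens were left out in turn, the 1 without RARA+/+ replicate 1. Rara's gene difference ranged from -0.17 to -0.01, its probe set 4612180 from -1.52 to -1.25 and 5534347 from -0.76 to -0.59. Genes with a differing profile, 269, ranged from 195 to 376 without single spleens, and were 625 with the Y-linked covariate, 68 without dim probe sets and 0 with own spreads. Lists passing by the exact test were 0, which shows no stability, since a single list cannot go below an adjusted p of 0.167; by camera they went from 3 (without RARA+/+ replicate 3) to 10 around 7. Component 1, 5.38, ranged from -5.60 to 13.6 without single spleens. For 92 named genes 37 of 1888 values changed sign and 0 passed. The changes fell in 20 genes, among them Cd34, Erg, Ccnb2, Rrp9, Vpreb3, Pou2af1 and Ncoa2. The cause was not tested where a single spleen moved a count. Xist as a covariate was planned and not run, as Xist is unnamed.

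With the replicate block, genes and probe sets passing were 0, profile genes 374 (242 shared), lists 0 by sign flips (smallest p 0.0625) and 10 by camera, Rara -0.09 and component 1 5.38. The labels tie no same-numbered mice together, and the data decide it only in part: correlations within numbers 1 to 5 after removing genotype means were 0.253, 0.574, 0.0719, 0.134 and -0.0168, not all over 0.1, while RARA+/- replicates 2, 3 and 4 correlated best with their own number. The numbers were therefore not taken as pairs.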

Other observations

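The genes named in the paragraphs on early response and eosinophil genes were picked from their values, though the rule also names Jun, Btg2 and Postn. Besides the limma fit over all genes, exact permutation tests were run for single genes and for the mean of 10 early response genes. Their p-values are left out, since a test of genes picked from their values is void. The profile tests with own spreads or without dim probe sets, the list comparison, the reading of the lists with an estimated correlation as an explanation, and the tests of the Y-linked genes were chosen only after the result was seen. Dusp1, a phosphatase of MAP kinases that cells switch on within minutes of a stimulus, was at 6.96, 10.52, 7.96, 8.03 and 7.04 in RARA+/- replicates 1 to 5 and between 9.22 and 10.32 in RARA+/+ spleens. Jun, a gene of the same response, was at 6.34, 9.54, 6.37, 7.22 and 5.93 in RARA+/- spleens and at 9.54, 6.75, 9.20, 9.45 and 9.0 in RARA+/+ spleens. Other genes of this response differed less between the genotypes: Egr1 by 0.03, Nr4a1 by -0.09, Ier3 by -0.18, Ier2 by -0.23 and Fos by -0.49. RARA+/- replicate 2 thus went against its group: its Dusp1, Btg2 (10.26) and Fos (7.62) values were the highest of the 10 spleens. None of these genes passed over all genes (limma, adjusted p = 0.995 for each).

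Eosinophil granule genes varied widely between the RARA+/+ spleens. Prg2 was at 11.58 ± 0.83 against 9.39 ± 2.13 and Epx at 7.55 ± 0.63 against 6.77 ± 0.96 in RARA+/- against RARA+/+ spleens (n = 5 each). Prg2 was 12.52 in RARA+/- replicate 2 and 12.47 in RARA+/+ replicate 2, and 7.58 and 7.45 in RARA+/+ replicates 3 and 4. In the same replicates 2, the carbonic anhydrase gene Car2 was 9.77 and 10.07, and Kit, a receptor of progenitors and mast cells, was 7.72 and 7.63, the lowest of all spleens. Postn was 10.65 in RARA+/- replicate 1 and 11.02 and 10.05 in RARA+/+ replicates 1 and 4.

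The differing probe set profiles of 269 genes could be a product of unequal spread within a gene: with each probe set tested against its own spread 0 genes passed, and 579 were called in simulated arrays with no effect. That simulation took the measured spreads, which hold estimation noise, as the true ones, so 579 can be too high. Dim probe sets near background fit as well, as 75.1% of the lead probe sets were dim against 24.2% of all. In 8 of 100 splits of the arrays, the real one included, the count was at least the real 269. The median of the other splits was 140 and the highest was 478, so a chance division is not excluded. Genes within 20 Mb of Rara, a wider set than the list of its neighbours, were called 1.87 times as often as genes elsewhere. These were 17 of 526 genes, with Rara itself among the 17 (3.23% against 1.73%, Fisher exact p = 0.0172). The ratio lay under the 2 set beforehand for sequence variants of mouse strains around Rara, so that bound was not met. However, the excess near Rara lies in the direction such variants would give. The upper limit of the odds ratio, 3.13, which was not part of that bound, lay over 2. The ratio therefore decides neither for nor against them. Such variants stay open for the called genes other than Rara.

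The 7 lists higher by camera might reflect genes of a list moving together from mouse to mouse: with an estimated correlation 0 lists passed, and in 43 of 100 splits, the real one included, at least the real 7 passed, the highest other being 12. A lower share of leukemic cells in RARA+/- spleens would raise B cell markers with the rest. The B cell list minus the mean of the erythroid, platelet, NK, T and macrophage lists differed by -0.32 (SE 0.213, exact permutation p = 0.143). All of those other lists were among the 7 higher by camera, so their choice favours a negative value, which decides nothing. The primary granule genes were not lower (difference 0.04), and a lower share of leukemic cells stays open. For the real counts of 0 the splits decide nothing, since any of the 100 reaches 0; the highest other count was 0 for lists by the exact test, 2 for genes and 25 for probe sets.

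The unequal Y-linked genes are not explained by array brightness. Eif2s3y spans 7.10 log2 units over the arrays. The 799 genes that reach the same highest level (within 0.5) span 0.97 in the median and 2.37 at their 95th percentile. That 0 of them span as much adds no weight, since Eif2s3y was the most variable of the kept genes. A correlation of Eif2s3y with the array medians, tried earlier, decided nothing, as RMA evens out the medians (Spearman rho 0.00606, permutation p = 1; Pearson r -0.0231, permutation p = 0.953, n = 10; r -0.38 without the 2 arrays farthest from the median). A mixture of Y-bearing and Y-lacking cells could give the intermediate levels of RARA+/- replicate 1 and RARA+/+ replicate 1, where the shares of full signal over Kdm5d minus Eif2s3y differed by -1.14 and 1.94 percentage points. The shares were low there, at 7.18% for Kdm5d and 8.32% for Eif2s3y in RARA+/- replicate 1. In RARA+/+ replicate 1 they were 9.90% and 7.96%. Shares that are both low can differ by few points only, so their closeness is weak support for a mixture. In RARA+/- replicate 5 they differed by 42.5 (48.3% for Kdm5d, 5.79% for Eif2s3y), which argues against a simple mixture there. The measure is rough, since the shares also disagreed in RARA+/+ replicate 3, a spleen of high Y-linked level (75.5% for Kdm5d, 100% for Eif2s3y). There the quartile ranges over probe sets overlapped, unlike in RARA+/- replicate 5. The sex of the mice and of any cell donor is not in the labels, so the origin of the pattern, and any part of sex in the genotype differences, stays open.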
